A study of Rattus rattus with 10 samples.

How the data were processed

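RNA of whole testis was profiled on 10 Affymetrix Rat230_2 arrays, which carry 31099 probe sets. Per the labels, the testes came from Long-Evans males given 1 intraperitoneal dose of gamendazole (6 mg/kg), lonidamine (25 mg/kg) or the DMSO vehicle. There was 1 array for each treatment at 4, 12 and 24 h, and 1 more vehicle array at 0 h. The labels state neither how many animals were behind an array nor whether RNA was pooled. Their organism field names Rattus rattus, while Long-Evans is a strain of the laboratory rat, and nothing in the values depends on that field.

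Per the labels' protocols, RNA was extracted with TRIzol, copied and labelled with biotin by the single-cycle procedure, and the arrays were read with GCOS 1.1, per the submitters' processing notes. The deposited values are linear intensity per probe set. By the values themselves, the authors' software scaled every array to 1 trimmed mean of 500 with 2% trimmed at each end, so that differences in total RNA between arrays were removed before deposit. No detection calls were used here. Array medians lay between 110.2 and 124.5 units of signal. The arrays were grouped here into 3 hybridisation runs from the instrument records deposited with them, and whether these match the laboratory's own batches is not known; results that use the run rest on this grouping. The first held vehicle 0 h, vehicle 4 h and lonidamine 4 h. The second held gamendazole 4 h and the 12 h arrays, and the last held the 24 h arrays. By this grouping gamendazole 4 h was the only treated array hybridised in another run than its vehicle array of the same hour.

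From these values, 57 control probe sets were left out and 31042 used. Values under the pooled 25th percentile (37.1) were set to it, and log2 was taken. Values at that floor have no order, so a fold is written as at least that large where its lower side lay at the floor on 1 or more of the arrays compared, and log2 differences of such genes are bounds too. Tests used the 17549 probe sets at or above the pooled median (116.2) on 2 or more arrays. Gene names came from the platform's annotation table: 20826 probe sets had 1 symbol, 436 had several and stayed unnamed, and 9780 were not listed. The named probe sets covered 14217 genes, of which 10508 were tested. A second gene table shared 0 identifiers with the annotation and was not used. Each gene is given by its brightest probe set.

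There were no replicates of a treatment at an hour. For the averaged comparisons, limma 3.58.1 in R 4.3.3 was fitted to the 9 arrays of 4, 12 and 24 h with treatment and hour as factors, leaving 4 residual degrees of freedom. The eBayes step used a variance trend, p-values were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. The hours serve as replicates in this fit, so an effect that changes with the hour counts as spread. In a second fit each treated array was set against all 4 vehicle arrays pooled over the hours. It had 3 residual degrees of freedom, all from vehicle arrays, and assumes that a treated array varies as vehicle arrays do. The 28 tested probe sets at the floor on all 4 vehicle arrays have no spread of their own there by construction. Their p-values rest on the spread that eBayes borrows from other probe sets in this second fit. Folds printed for single hours are ratios to the vehicle array of the same hour, so they are not the estimates that this fit tested. P-values of these 2 fits therefore rest on hours or on vehicle arrays as stand-ins for replicates, and measure a spread that may be partly technical. Without a test, probe sets at least 2-fold from the vehicle array of the same hour were counted where the brighter array reached the pooled median, and the 6 pairs of vehicle arrays gave the background. The number of arrays limits the precision: the median 95% interval of an averaged log2 difference reached 0.40 to either side.

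The 25 gene lists were fixed before the data were examined, as were the fits, thresholds and naming rule. They cover the IL-1 and NF-kB response, HSP90 and heat shock, eEF1A and translation elongation, immediate early genes, acute phase and interferon, and Sertoli-germ cell adhesion with the blood-testis barrier. Lists of cell markers cover Sertoli cells, Leydig cells with steroidogenesis, spermatogonia, meiotic spermatocytes, round and elongating spermatids, peritubular and smooth muscle, macrophages and leukocytes, endothelium, erythrocytes, and epididymal epithelium. The remaining lists cover glycolysis and lactate transport, NRF2 and xenobiotic response, ER and integrated stress, glucocorticoid response, the circadian clock, cholesterol synthesis, p53 and apoptosis, and growth factors of the tubule. Lists with 5 or more tested genes were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation and fry stand beside it. For single hours, each list's median was placed among 10000 random lists of the same size and brightness, as a description of those arrays.

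Genes were named by rule among those with exactly 1 symbol. The rule took the 3 highest and 3 lowest ratios for each drug and hour that lay outside the range of the 4 vehicle arrays, and the 8 highest and 8 lowest averaged differences that passed for each drug. It took 5 and 5 for the direct comparison of the drugs, up to 4 members of each list, and the 5 genes of widest vehicle range with the clock genes. Where fewer passed, places were filled by smallest p among genes of 1 sign at all 3 hours, and these are said not to pass. Il1a, Il1b, Hsp90aa1, Hsp90ab1, Eef1a1 and Inhbb were always included; Hsp90aa1 had no probe set of its own.

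The averaged fit was tested on simulated data over 17549 probe sets with the arrays' own spread. Noise was drawn independently for each probe set and array, without hour effects, and a change was equal at all hours. These are the assumptions of the fit, so the recovery does not cover effects that change with the hour. For gamendazole against vehicle it called 46 of 67 probe sets changed 2-fold (68.7%), 66 of 67 changed 4-fold and 12 of 17349 unchanged. For lonidamine it called 49 of 67 changed 2-fold (73.1%), 65 of 67 changed 4-fold and 11 of 17349 unchanged. The fit of gamendazole 24 h against the vehicle arrays called 41 of 67 changed 2-fold (61.2%), 66 of 67 changed 4-fold and 11 unchanged. The list test called a shifted list of 25 genes and 1 of 20 random lists. Their genes were simulated without correlation, whereas the estimated correlation in the data was 0.364 for the IL-1 and NF-kB list and 0.471 for the acute phase list.

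Alternatives were other normalizations (quantile, cyclic loess), other floors and filters, eBayes without the trend, no hour factor, the 0 h vehicle array added, a 3' to 5' ratio as covariate, each hour or vehicle array left out, all probe sets of a gene, and other list tests. Alternatives chosen after seeing the data were the hybridisation run in place of the hour as a factor (on the same 9 arrays, and on 10 with the 0 h vehicle array), gamendazole 4 h left out, probe sets at the floor on all vehicle arrays left out, each treated array alone against 3 vehicle arrays, and comparisons of the 24 h with the 4 h arrays.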

Results

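Transcripts of rat testis were measured on 10 arrays, 1 for each treatment and hour. Gamendazole and lonidamine are indazole carboxylic acids with a dichlorobenzyl group; gamendazole also carries an acrylic acid side chain and a trifluoromethyl group. Both disturb the attachment of developing sperm cells to Sertoli cells, the nurse cells of the seminiferous tubule. Gamendazole was given at 6 mg/kg and lonidamine at 25 mg/kg, and testes were taken at 4, 12 and 24 h, with vehicle arrays at these hours and at 0 h. The doses differ, so differences between the drugs are differences between these 2 treatments. No treatment was replicated at an hour. Vehicle arrays correlated with each other at r between 0.9768 and 0.9789 over log2 signals, and with gamendazole 24 h at r between 0.9429 and 0.9461. The ratio of 3' to 5' signal of beta-actin, a measure of RNA integrity, lay between 1.85 and 2.0 on all arrays. That of GAPDH lay between 0.723 and 0.853 and was highest on gamendazole 24 h.

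The first comparison asked which transcripts differed from vehicle after gamendazole, averaged over the 3 hours (n = 3 arrays per treatment). Ccl2, a chemokine that draws monocytes, was at least 30.6-fold higher (log2 4.93 ± 0.54 standard error, limma adjusted p = 0.00314), and Cxcl1, a chemokine for neutrophils, at least 19.8-fold (4.31 ± 0.49, adjusted p = 0.00345). The beta-tubulin gene Tubb6 rose at least 18.2-fold (4.19 ± 0.34, adjusted p = 0.00135), and Hpx, which encodes the haem-binding plasma protein hemopexin, rose 17.6-fold (4.13 ± 0.57, adjusted p = 0.00667). Tnfrsf12a, the receptor of the cytokine TWEAK, rose 21.3-fold, Testin, a secreted protein of Sertoli cell junctions, at least 14.3-fold, the interferon-induced chemokine Cxcl11 at least 11.2-fold, and the chemokine Ccl20 at least 12-fold. Vehicle signals of Ccl2, Cxcl1 and Ccl20 lay at the floor at these 3 hours, and those of Tubb6, Testin and Cxcl11 at 1 of them.

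Nat8f5, of the N-acetyltransferase family, was at least 5.71-fold lower with gamendazole (log2 -2.51 ± 0.43, limma adjusted p = 0.0151), with its signal at the floor at 12 and 24 h. Smtnl2, a smoothelin-like gene, fell by 2.34 ± 0.28 on the log2 scale. Pde9a, a phosphodiesterase of cyclic GMP, fell by 1.89, Cxcr4, the receptor of the chemokine Cxcl12, by 1.76, and the mitochondrial carrier Slc25a45 by 1.71. Camsap3, which binds microtubule minus ends, fell by 1.56, Ccdc126 by 1.53 and the cell cycle inhibitor Cdkn1b by 1.40. Inhbb, the beta B subunit of inhibin and activin made by Sertoli cells, fell by 1.30 ± 0.21, or 2.47-fold (adjusted p = 0.0119).

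In all, 693 of 17549 probe sets passed, 610 higher and 83 lower, and 3512 had an unadjusted p under 0.05. All 693 had the same sign at 4, 12 and 24 h, which a fit with the hours as replicates favours, so this is no separate evidence. With the hybridisation run, inferred from instrument records, in place of the hour as a factor on the same 9 arrays the count was 205 (188 higher, 17 lower), and with the 0 h vehicle array added as well it was 272. With gamendazole 4 h left out it was 1162, of which 671 were higher and 491 lower. Without the 4 h arrays it was 1646, with 1045 higher and 601 lower, without the 24 h arrays 186 and without the 12 h arrays 0 (limma; 1642 at an unadjusted p under 0.05). It was 0 with no filter on low signals (limma; 4099 at an unadjusted p under 0.05), 28 without the variance trend, 247 with a floor at the 50th percentile, 372 without the hour and 242 with the actin ratio as covariate.

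The IL-1 and NF-kB list and the immediate early list had the largest medians with gamendazole. Of 28 tested genes of the IL-1 and NF-kB response, 14 rose and 0 fell (20 rose and 1 fell when adjusted over the list alone), with a median log2 difference of 1.52 (camera adjusted p = 8.08e-15). The estimated correlation did not keep this call (camera adjusted p = 0.356), while fry did (fry adjusted p = 0.0439). Il1a, which encodes the cytokine interleukin 1 alpha, rose 8.02-fold (log2 3.00 ± 0.30, limma adjusted p = 0.00203), while Il1b differed by 0.89 ± 0.44 and did not pass (adjusted p = 0.3). Of 32 immediate early genes, which are transcribed within minutes of a stimulus, 17 rose and 0 fell (22 when adjusted over the list alone; median 1.12, camera adjusted p = 4.74e-18, adjusted p = 0.217 with an estimated correlation). Ier3 rose 9.02-fold, the AP-1 subunit Fos at least 8.50-fold, Gadd45b at least 7.76-fold and the transcription factor Egr1 6.22-fold. The vehicle signal of Fos was at the floor at 4 and 12 h.

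Of 20 acute phase and interferon genes, 2 rose with gamendazole (9 when adjusted over the list alone; median 0.86, camera adjusted p = 1.37e-06, adjusted p = 0.356 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose 10.1-fold and the transcription factor gene Stat3 3.39-fold. Of 26 macrophage and leukocyte genes, 2 rose (4 when adjusted over the list alone; median 0.55, camera adjusted p = 1.38e-05, adjusted p = 0.356 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils and monocytes, rose at least 4.41-fold over vehicle signals at the floor at 4 and 24 h; the other was the complement gene C1qa, chosen after its values were seen, by 0.87 on the log2 scale. Hbb, the beta-globin of red cells, rose 2.06-fold beside them (log2 1.04 ± 0.20, limma adjusted p = 0.0242), and the other 3 tested erythrocyte genes did not pass.

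Of 40 genes of Sertoli-germ cell adhesion and the blood-testis barrier, 10 rose with gamendazole and 0 fell (12 rose and 1 fell when adjusted over the list alone; median 0.15, camera adjusted p = 0.000797, adjusted p = 0.288 with an estimated correlation). Besides Testin, the protease inhibitor Timp1 rose 7.70-fold, and the integrin subunits Itga6 and Itgb1 rose 5.09-fold and 3.77-fold. Elongating spermatid genes were lower by a median of log2 -0.13 over 23 genes (camera adjusted p = 2.93e-07, adjusted p = 0.356 with an estimated correlation). The call ended under quantile normalization (adjusted p = 0.158) and cyclic loess (0.938). No gene of that list passed, and 16 were lower when adjusted over the list alone. Among them, the protamine Prm2 differed by -0.25 ± 0.06 (limma adjusted p = 0.0513) and the sperm tail protein Akap4 by -0.21 ± 0.06. Meiotic spermatocyte genes had a median of -0.16 over 16 genes (camera adjusted p = 0.00127, adjusted p = 0.356 with an estimated correlation; 0 passed, 6 lower when adjusted over the list alone), and under quantile normalization and cyclic loess the adjusted p was 0.0658 and 0.0527. Round spermatid genes had a median of -0.09 over 13 genes (camera adjusted p = 0.0358, adjusted p = 0.356 with an estimated correlation; 0 passed, 2 lower when adjusted over the list alone), and under quantile normalization the adjusted p was 0.864, while cyclic loess turned the direction (0.981). Without the 4 h or 24 h arrays the round spermatid call ended too (camera adjusted p = 0.0879 and 0.146). It held in 7 of 14 alternatives other than fry. The elongating spermatid medians with gamendazole were -0.04, -0.12 and -0.21 at 4, 12 and 24 h. Random lists of equal brightness had medians of -0.04, -0.13 and -0.17. At 24 h the meiotic median was -0.17 against -0.12 for random lists, and the round spermatid median -0.18 against -0.14.

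Genes of the chaperone HSP90 and of the translation factor eEF1A formed lists of their own. Hsp90ab1 differed by 0.15 ± 0.07 with gamendazole and 0.08 ± 0.07 with lonidamine, and Eef1a1 by -0.06 ± 0.04 and -0.12 ± 0.04; none passed. Of 25 heat shock genes 2 rose with gamendazole (5 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.113, but 0.00878 and called higher under quantile normalization and 0.0103 under cyclic loess), namely the small heat shock protein Cryab by 4.18-fold and the chaperone Hsph1 by 1.39-fold. Of 12 elongation genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.287). Of 19 Sertoli cell markers, the lysosomal protease Ctsl rose 2.42-fold and Inhbb fell (3 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.587). Of 9 spermatogonial genes, Itga6 rose and the transcription factor Dmrt1 fell by 0.79 (the same count when adjusted over the list alone; camera adjusted p = 0.611).

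The other cell markers were not called as lists with gamendazole. Of 16 Leydig cell genes, 2 rose (4 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.914, but 0.00992 and called higher without the 24 h arrays), namely Akr1c14, an enzyme of steroid metabolism, by 2.61-fold, and Hsd11b1, chosen after its values were seen, by 0.55 on the log2 scale. Of 11 peritubular and smooth muscle genes, the actin-binding protein gene Tagln rose 2.36-fold (3 rose when adjusted over the list alone; camera adjusted p = 0.101). Of 10 endothelial genes 0 passed, also when adjusted over the list alone (camera adjusted p = 0.639). The erythrocyte and epididymal lists had 4 and 3 tested genes and were not tested as lists. Of the epididymal genes the keratin Krt19 rose 3.37-fold and Epcam fell by 0.39, the same count when adjusted over the list alone. The list median and the direction of the test differed in sign for the Leydig, ER stress and clock lists, and the median and mean for spermatogonia; none of these 4 lists was called.

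**Figure D1:**
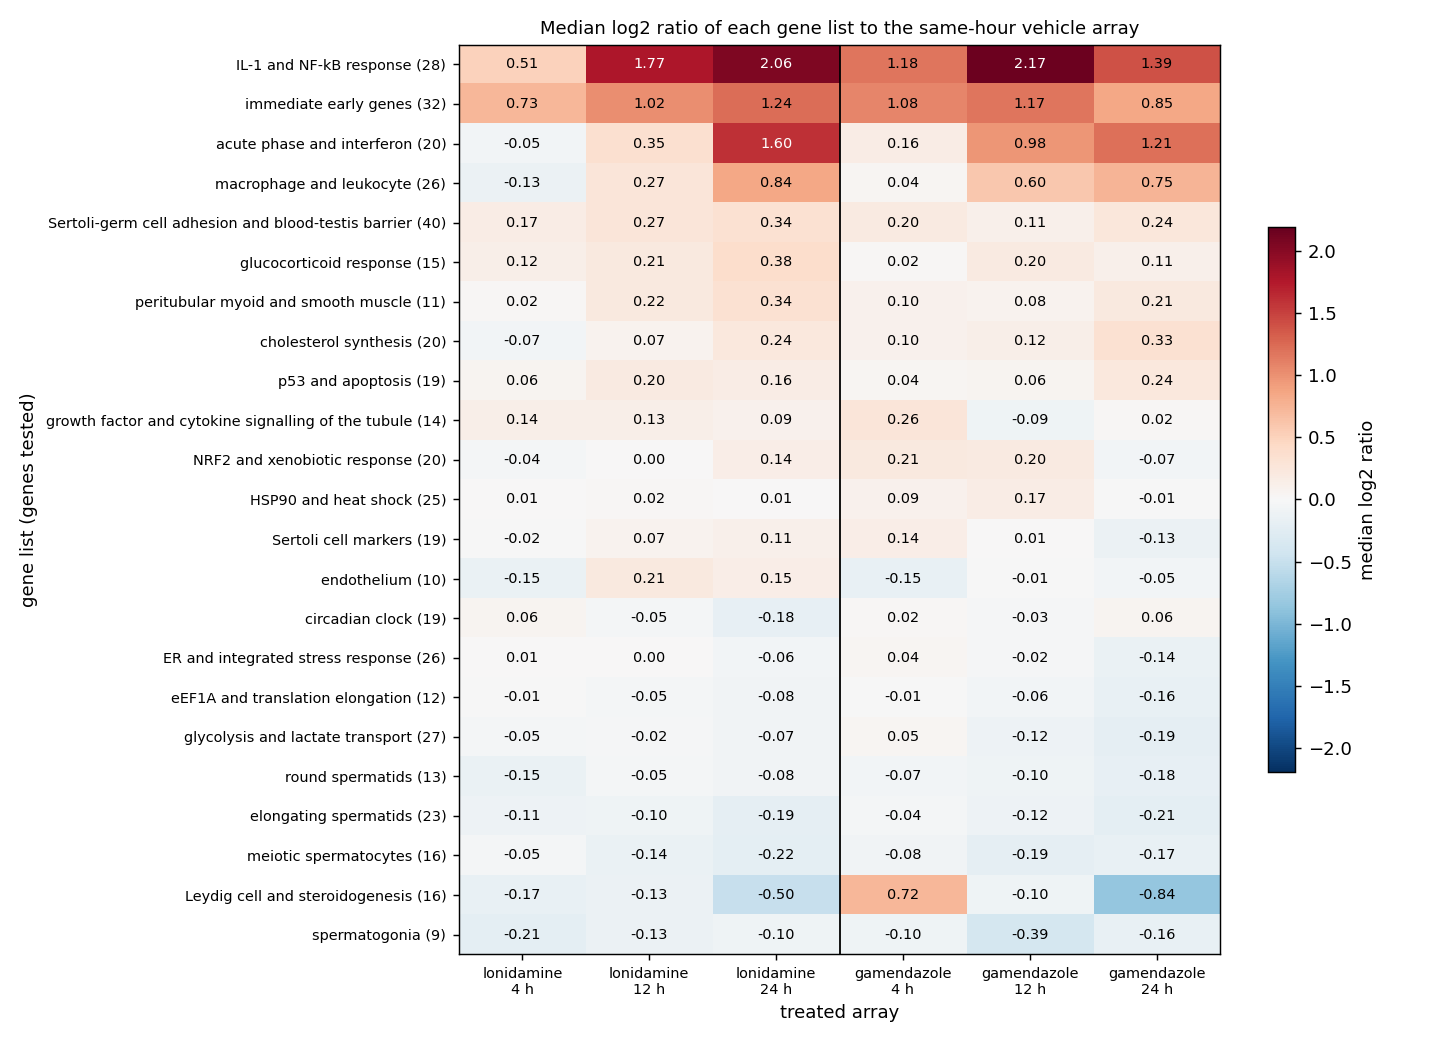
Heat map of the median log2 ratio of each gene list (vertical, with the number of genes tested) to the vehicle array of the same hour, on each treated array (horizontal), with red for higher and blue for lower. The IL-1 and NF-kB list lies at 1.18, 2.17 and 1.39 with gamendazole and at 0.51, 1.77 and 2.06 with lonidamine.

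In the same comparison for lonidamine, Cxcl1 was at least 24.8-fold higher (log2 4.63 ± 0.49, limma adjusted p = 0.00673) and Ccl2 at least 22.9-fold (4.52 ± 0.54, adjusted p = 0.0104). Cxcl11 rose at least 11.5-fold, Hpx 10.4-fold and Ripk2, a kinase that feeds NF-kB signalling, 9.84-fold (3.30 ± 0.31, adjusted p = 0.00488). Tnfrsf12a rose 8.92-fold, Fos at least 8.83-fold and Il1a 8.50-fold (3.09 ± 0.30, adjusted p = 0.00488). Tubb6 rose at least 7.79-fold. The only named gene that fell was Nat8f5, at least 6.10-fold lower (-2.61 ± 0.43, adjusted p = 0.033). The genes next in line did not pass: the sperm cell lipid-binding gene Fabp9 differed by -0.19 ± 0.04 (adjusted p = 0.0536), Daxx by -0.61 ± 0.12 and Rbm24 by -1.79 ± 0.38.

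With lonidamine 137 probe sets passed, 135 higher and 2 lower, and 2235 had an unadjusted p under 0.05. All 137 kept 1 sign over the 3 hours, which the fit again favours. With the run in place of the hour the count was 92 on the same 9 arrays and 110 with the 0 h vehicle array added as well, and with gamendazole 4 h left out it was 225, of which 188 were higher and 37 lower. Without the 4 h arrays it was 600, with 542 higher and 58 lower, without the 24 h arrays 19 and without the 12 h arrays 0 (limma; 1166 at an unadjusted p under 0.05). It was 0 with no filter (limma; 2775 at an unadjusted p under 0.05), 1 with a floor at the 50th percentile, 55 with a stricter filter, 2 without the variance trend, 50 without the hour and 4 with the actin ratio as covariate.

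Of the 28 IL-1 and NF-kB genes, 9 rose with lonidamine (20 when adjusted over the list alone; median 1.60, camera adjusted p = 4.85e-21, adjusted p = 0.204 with an estimated correlation). Of the immediate early genes 11 rose (18 when adjusted over the list alone; median 1.13, camera adjusted p = 1.1e-21, adjusted p = 0.0868 with an estimated correlation), among them Ier3 by 7.19-fold and Egr1 by 6.27-fold. Adhesion and barrier genes had a median of 0.23, with 2 risen (11 when adjusted over the list alone; camera adjusted p = 5.42e-07, adjusted p = 0.0868 with an estimated correlation). The 2 were the focal adhesion genes Vcl and Zyx, by 0.57 and 0.76 on the log2 scale, chosen after their values were seen. Itgb1 differed by 1.44 ± 0.28 (limma adjusted p = 0.0526), Itga6 by 1.89 ± 0.38 and Testin by 2.55 ± 0.67 (adjusted p = 0.136), and these 3 did not pass. Acute phase genes had a median of 0.64, with 0 passing (4 when adjusted over the list alone; camera adjusted p = 3.47e-08, adjusted p = 0.277 with an estimated correlation). Macrophage and leukocyte genes had a median of 0.33, with 0 passing (1 when adjusted over the list alone; camera adjusted p = 0.00325, adjusted p = 0.453 with an estimated correlation). The call ended with the filter at the 75th percentile (camera adjusted p = 0.129). It also rested on the 24 h array: without the 24 h arrays the camera adjusted p was 0.74, and at 4 h the median was -0.13 with 18 of 26 genes lower. Hbb differed by 0.47 ± 0.20 beside them and did not pass (limma adjusted p = 0.377).

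Peritubular and smooth muscle genes were called higher as a list with lonidamine, with a median of 0.19 and 0 passing (2 when adjusted over the list alone; camera adjusted p = 0.00608, adjusted p = 0.277 with an estimated correlation, and 0.09 without the 24 h arrays). So were glucocorticoid response genes, with a median of 0.35 and 1 risen (4 when adjusted over the list alone; camera adjusted p = 0.00253, adjusted p = 0.204 with an estimated correlation). The 1 was Dusp1, a phosphatase that switches off MAP kinases, by 2.31-fold. Dusp1 is also on the immediate early list, as is Sgk1, so these lists are not separate evidence. Elongating spermatid genes had a median of -0.13 (0 passing, 10 lower when adjusted over the list alone; camera adjusted p = 7.03e-10, adjusted p = 0.277 with an estimated correlation). Meiotic genes had a median of -0.12 (0 passing, also when adjusted over the list alone; camera adjusted p = 0.000769, adjusted p = 0.277 with an estimated correlation). Round spermatid genes had a median of -0.07 (0 passing, 3 lower when adjusted over the list alone; camera adjusted p = 0.00516, adjusted p = 0.277 with an estimated correlation, and 0.0874 without the 4 h arrays). All 3 calls ended under quantile normalization and cyclic loess, with adjusted p of 0.319 and 0.6 for elongating spermatids, 0.158 and 0.0733 for meiotic genes and 0.592 and 0.511 for round spermatids. The elongating spermatid medians with lonidamine were -0.11, -0.1 and -0.19 at 4, 12 and 24 h. Random lists of equal brightness had medians of -0.09, -0.08 and -0.13. At 24 h the meiotic median was -0.22 against -0.1 for random lists, and the round spermatid median -0.08 against -0.11.

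Lists not called with lonidamine included the heat shock genes (0 passing, 1 higher when adjusted over the list alone; camera adjusted p = 0.284, but 0.0339 and 0.0449 and called higher under quantile normalization and cyclic loess) and the elongation genes (0 passing either way; camera adjusted p = 0.163). Of the Sertoli cell markers Ctsl rose 1.73-fold (2 when adjusted over the list alone; camera adjusted p = 0.0515, but 0.0198 and 0.0282 and called higher under these normalizations, and 0.0251 without the 24 h arrays). Of the Leydig cell genes Akr1c14 rose 2.90-fold (2 when adjusted over the list alone; camera adjusted p = 0.619). Of the spermatogonial genes 0 passed (1 higher when adjusted over the list alone; camera adjusted p = 0.726), and of the endothelial genes 0 passed either way (camera adjusted p = 0.133). None of the erythrocyte or epididymal genes passed; adjusted over the list alone, 1 epididymal gene was higher and 1 lower. List median and test differed in sign for the ER stress and clock lists, and median and mean for spermatogonia.

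**Figure D2:**
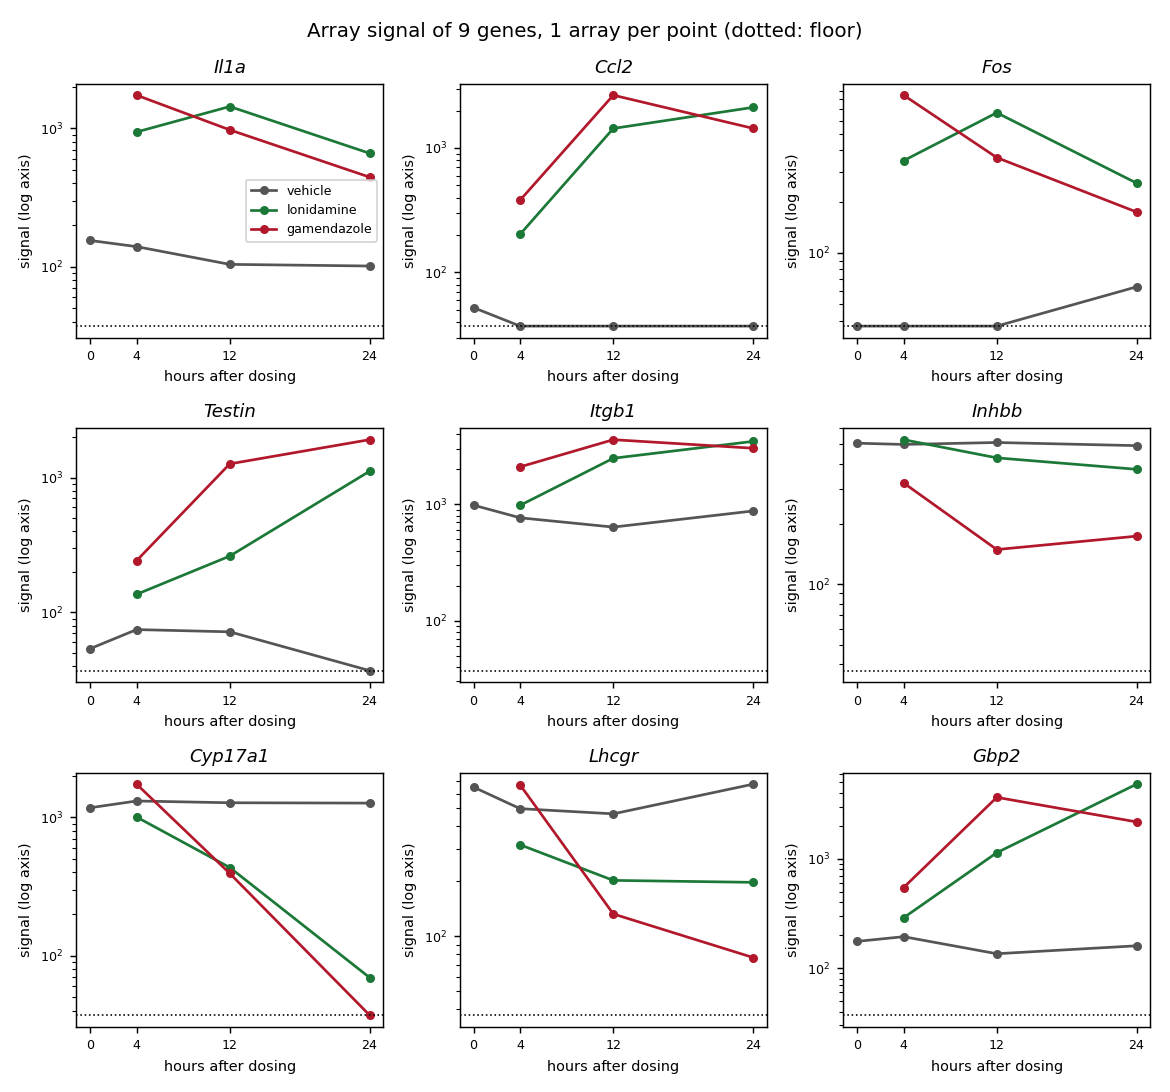
Signal of 9 genes (log axis) against hours after dosing, 1 array per point, for vehicle, gamendazole and lonidamine, with signals under the floor of 37.1 (dotted) drawn at it. Ccl2 reaches 2656.4 with gamendazole at 12 h, and Cyp17a1 drops to the floor with gamendazole at 24 h.

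The direct comparison asked whether gamendazole at 6 mg/kg differed from lonidamine at 25 mg/kg. No probe set passed (limma, 0 of 17549; 776 at an unadjusted p under 0.05; smallest adjusted p 0.722). This does not show that the drugs act alike, since the median 95% interval reached 0.40 on the log2 scale to either side. Nmu, Gla, Mat2b, Slc3a1 and Gucy1a1 were named for a small unadjusted p and did not pass, so that their intervals, which are not adjusted, leave out 0 by that choice. The neuropeptide gene Nmu differed by 1.85 (95% interval 1.1 to 2.6). The lysosomal galactosidase gene Gla differed by 1.38 (0.77 to 2.0) and Mat2b, a subunit of methionine adenosyltransferase, by 0.65 (0.42 to 0.89). Inhbb, named beforehand, differed by -1.11 (-1.58 to -0.65) and did not pass either. It fell with gamendazole and differed by -0.19 ± 0.21 with lonidamine. The amino acid transporter gene Slc3a1 differed by -1.64 (-2.28 to -0.99) and Gucy1a1, a subunit of the nitric oxide receptor, by -0.88 (-1.31 to -0.45). For Il1a the difference was -0.08 (-0.76 to 0.59) and for Ccl2 0.41 (-0.80 to 1.63).

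Among the lists, macrophage and leukocyte genes were called higher with gamendazole than with lonidamine, by a median of 0.26 over 26 genes (camera adjusted p = 0.0132, adjusted p = 0.999 with an estimated correlation, 0.0644 without the 4 h arrays, 0.225 without the 12 h arrays and 0.0588 with the run in place of the hour on the same arrays). This call held in 8 of 14 alternatives other than fry. Endothelial genes were called lower, by a median of -0.57 over 10 genes, a call kept in 8 of 13 alternatives other than fry (camera adjusted p = 0.0206, adjusted p = 0.999 with an estimated correlation, 0.22 without the 12 h arrays and 0.317 without the 24 h arrays). Their largest members were Cldn5, a tight junction protein, which differed from vehicle by -1.17 ± 0.43 with gamendazole and -0.31 ± 0.43 with lonidamine, and the VEGF receptor gene Kdr, at -0.66 ± 0.38 and 0.03 ± 0.38. No member of either list passed, also when adjusted over the list alone. Of the other lists, adjusted each alone, Sertoli cell markers had 1 gene lower, growth factors of the tubule 2 lower and ER stress 1 higher. Genes of the IL-1 and NF-kB response were not called as a list over the 3 hours (median 0.07, camera adjusted p = 0.988), but were called lower with gamendazole without the 4 h arrays (0.0313) and higher without the 24 h arrays (0.00917). Median and test differed in sign for that list and for Leydig cells, round spermatids and growth factors, none of them called. With gamendazole 4 h left out, 8 probe sets and 4 lists were called, and without all 4 h arrays 2 probe sets and 4 lists, with Sertoli cell markers and glycolysis genes called lower in both cases. Without the 12 h arrays 0 lists were called. Without the 24 h arrays 6 were, with Leydig cell, immediate early, acute phase and NRF2 genes called higher besides.

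The drugs' averaged effects were correlated across probe sets, which are not independent replicates (Pearson r = 0.81, Spearman 0.711). Unchanged simulated groups sharing the same vehicle arrays gave r = 0.501. The covariance was 0.136 against 0.0285 in the simulation, a difference of 0.1075. Per hour, r was 0.523 at 4 h, 0.66 at 12 h and 0.774 at 24 h, and the simulated value 0.5. With the vehicle arrays split between the drugs, r of the averaged effects lay between 0.587 and 0.609 over 6 splits. Of 610 probe sets risen with gamendazole and 135 with lonidamine, 131 were shared, and of 83 and 2 that fell, 1 was shared. Both lists rest on the same vehicle arrays, which raises the overlap, and no expected overlap was computed for that.

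**Figure D3:**
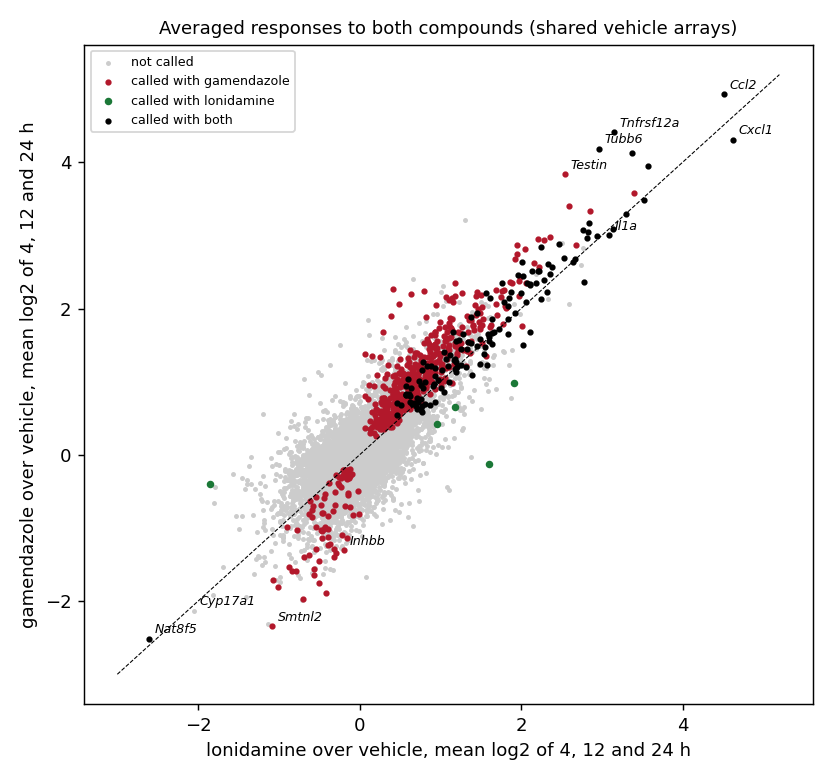
Averaged log2 difference from vehicle of each tested probe set, with lonidamine on the horizontal and gamendazole on the vertical axis, colours for probe sets called with gamendazole, lonidamine or both, and a dashed line of equal values. The values are correlated at r = 0.81, with 0.501 in simulated unchanged groups sharing vehicle arrays.

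Single hours were set against vehicle to follow the time course. Folds and log2 values of single hours are ratios to the 1 vehicle array of the same hour and were not tested themselves; passing and adjusted p come from the fit against the 4 vehicle arrays, whose estimate for a gene differs from that ratio. At 4 h, Cxcl1 was at least 46.1-fold higher with gamendazole and at least 21.2-fold with lonidamine, and Il1a was 12.5-fold and 6.76-fold higher. Against the 4 vehicle arrays the log2 estimates were 5.53 and 4.41 for Cxcl1 and 3.83 and 2.94 for Il1a. Vehicle signals of Cxcl1 lay at the floor, so that its spread in that fit was set by the floor. Fos was at least 22.8-fold higher with gamendazole (adjusted p = 0.0062) and at least 9.39-fold with lonidamine, which did not pass (adjusted p = 0.0671). Medians of the IL-1 and NF-kB list were 1.18 and 0.51, with -0.02 and 0.02 for random lists. Leydig cell genes had a median of 0.72 with gamendazole and -0.17 with lonidamine. The 4 h vehicle array was itself low for this list, with a median of -0.31 over 0 h. Gamendazole 4 h also lay in another inferred hybridisation run than that vehicle array. Of the lowest ratios at 4 h, Cpne7 differed by -2.51 with gamendazole, where its signal lay at the floor (-1.68 against the 4 vehicle arrays), and Uba7 by -2.33 with lonidamine (-1.98), and neither passed.

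Against the 4 vehicle arrays, 203 probe sets passed at 4 h with gamendazole (185 higher, 18 lower) and 12 with lonidamine (9 higher, 3 lower; 5 and 3 after quantile normalization). Each vehicle array against the other 3 gave 0 (limma; 631 to 1138 at an unadjusted p under 0.05), and each treated array alone against 3 vehicle arrays gave 0 to 30 with gamendazole and 0 to 5 with lonidamine. In the joint fit, leaving out vehicle 0 h, 4 h, 12 h or 24 h gave 132, 62, 33 and 63 with gamendazole, and leaving out vehicle 4 h, 12 h or 24 h gave 1, 1 and 2 with lonidamine. At least 2-fold from the same-hour vehicle array were 913 probe sets with gamendazole and 654 with lonidamine, against 510 to 658 between vehicle arrays. Gamendazole 4 h lay 2-fold from the vehicle array of its own run, that of 12 h, at 935 probe sets.

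At 12 h, the chemokine genes Ccl2 and Ccl20 stood further from vehicle than at 4 h. Ccl2 was at least 71.6-fold higher with gamendazole and at least 38.7-fold with lonidamine, Ccl20 at least 30.6-fold and 30.9-fold, and Tnfrsf12a 35.1-fold and 12-fold; all passed. Medians of the IL-1 and NF-kB list were 2.17 and 1.77. Zcchc18 was 10.8-fold lower with gamendazole (limma adjusted p = 0.000109) and 1.63-fold lower with lonidamine, which did not pass (adjusted p = 0.0687). Lrp8, a receptor of apolipoprotein E and reelin, was 8.01-fold lower with gamendazole (adjusted p = 0.000662) and differed by -0.55 with lonidamine (adjusted p = 0.526). The difference between the drugs was not tested at single hours. The counts were 1362 probe sets with gamendazole (861 higher, 501 lower) and 249 with lonidamine (224 higher, 25 lower; 320 and 43 under cyclic loess). Each array alone against 3 vehicle arrays gave 630 to 941 and 32 to 100. In the joint fit without vehicle 4 h, 12 h or 24 h the counts were 784, 676 and 791 with gamendazole and 101, 72 and 92 with lonidamine. At least 2-fold from vehicle were 1641 and 1002.

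At 24 h, 4 genes of the Leydig cell list were called lower with both drugs and 2 higher. Cyp17a1, which makes androgens in Leydig cells, was at least 34.2-fold lower with gamendazole (limma adjusted p = 2e-05) and 18.3-fold lower with lonidamine (adjusted p = 4.26e-05). Cyp11a1, which makes pregnenolone from cholesterol, was 19.8-fold and 4.41-fold lower (adjusted p = 0.000107 and 0.00116), and Lhcgr, the receptor for luteinizing hormone, 8.83-fold and 3.43-fold lower (adjusted p = 0.00109 and 0.0153). Against the 4 vehicle arrays the log2 estimates were -5.08 and -4.18 for Cyp17a1, -4.27 and -2.10 for Cyp11a1 and -2.88 and -1.52 for Lhcgr. Of 16 Leydig cell genes, 7 fell and 2 rose with gamendazole, and 4 fell and 2 rose with lonidamine; Star, which carries cholesterol into mitochondria and was chosen after its values were seen, was higher by 1.03 and 1.25 and passed in both. Cyp17a1 had also passed as lower at 12 h, by -1.70 and -1.56. The hydroxy acid oxidase gene Hao2 was 15-fold and 18.8-fold lower, and Nat8f5 at least 10.2-fold lower with both.

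At 24 h Testin, with the vehicle signal at the floor, was at least 51.5-fold higher with gamendazole and 30-fold with lonidamine, Hpx 37.7-fold and 40-fold, Ccl2 at least 38.8-fold and 57.1-fold, and Cxcl11 14.7-fold and 40-fold; all passed against the 4 vehicle arrays, where Testin had log2 estimates of 5.06 and 4.28 (5.69 and 4.91 over the 24 h array). Acute phase and interferon genes had medians of 1.21 and 1.60, with 11 and 16 of 20 genes called higher. Macrophage and leukocyte genes had medians of 0.75 and 0.84, with 10 and 9 of 26 called higher, and Hbb beside them was higher by 1.41 with gamendazole (limma adjusted p = 0.00834) and 0.49 with lonidamine (adjusted p = 0.18). The IL-1 and NF-kB medians were 1.39 and 2.06; gamendazole over lonidamine gave 0.66 at 4 h, 0.21 at 12 h and -0.54 at 24 h.

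The counts at 24 h were 1715 probe sets with gamendazole (998 higher, 717 lower) and 1229 with lonidamine (882 higher, 347 lower). Each array alone against 3 vehicle arrays gave 734 to 1277 and 522 to 868. In the joint fit without vehicle 4 h, 12 h or 24 h the counts were 1037, 818 and 1127 with gamendazole and 716, 616 and 760 with lonidamine. At least 2-fold from vehicle were 1735 and 1450. Without the variance trend the counts were 753 and 696. Under quantile normalization gamendazole had 824 higher and 514 lower, and under cyclic loess 1049 and 477; lonidamine had 740 and 266, and 1021 and 266.

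**Figure D4:**
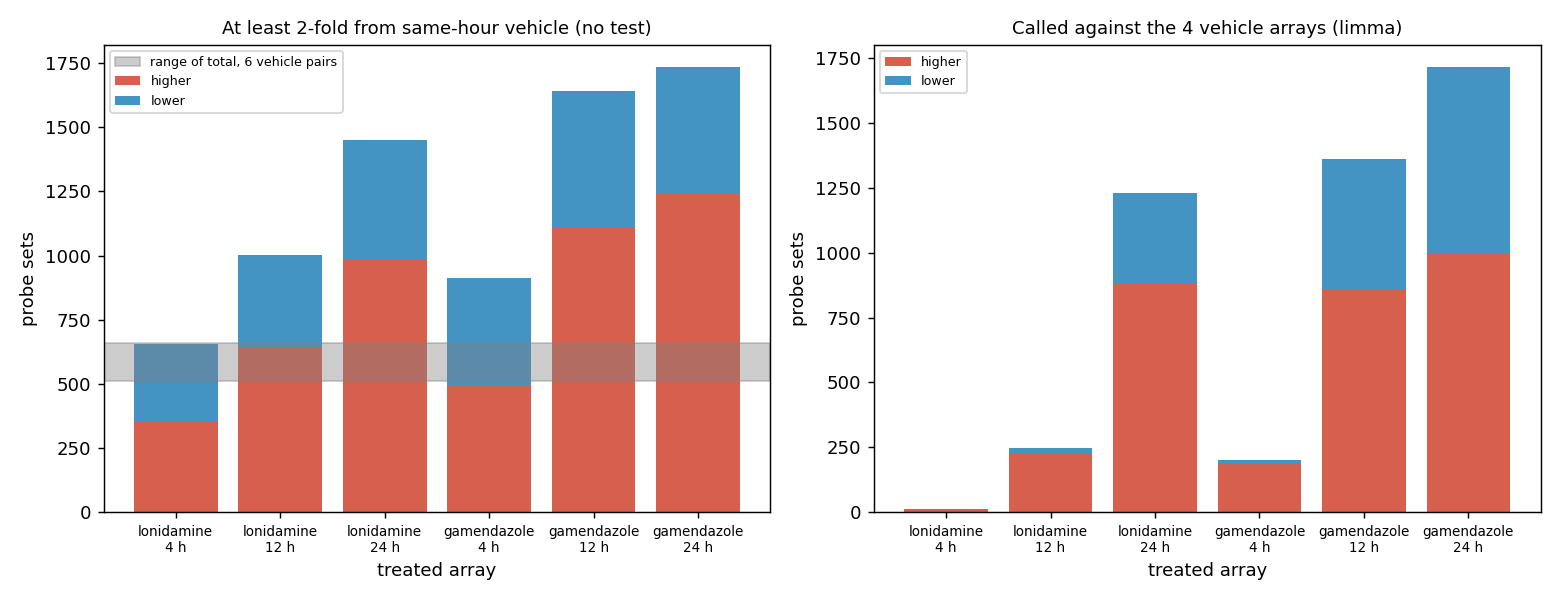
Stacked counts of probe sets higher and lower on each treated array, at least 2-fold from the same-hour vehicle array (left, with the range of vehicle pairs as a band) and called against the 4 vehicle arrays (right). The totals on the left run from 654 to 1735, with 510 to 658 for vehicle pairs, and those on the right from 12 to 1715.

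The vehicle arrays give the background of hour and handling. At least 2-fold from 0 h were 658 probe sets at 4 h, 592 at 12 h and 569 at 24 h. The IL-1 and NF-kB list had medians of 0.00 over 0 h at all 3 hours, and immediate early genes -0.01, -0.09 and -0.06. Leydig cell genes were lower than at 0 h by medians of -0.31 at 4 h and -0.29 at 12 h, where random lists had 0.00, and lay at 0.02 at 24 h. The genes of widest range were the digestive protease gene Ctrb1, with 3.59 on the log2 scale over the 4 arrays, RT1-CE16 of the major histocompatibility complex with 3.08, the collagen hydroxylase gene P4ha3 with 3.01, the histone methyltransferase gene Setd1b with 2.92 and Neurl1b with 2.80. RT1-CE16 was also among the highest ratios of lonidamine at 4 h (3.92, over a vehicle signal at the floor), and did not pass against the 4 vehicle arrays (3.10). Of the clock genes, Per1 ranged over 0.67, Bmal1 over 0.76, Dbp over 0.26 and Nr1d1 over 0.23.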

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

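All tests in this part were chosen after the result was seen. Treated arrays of 24 h were set against treated arrays of 4 h, both drugs in 1 fit with the vehicle arrays pooled (limma, 6 residual degrees of freedom), and 692 probe sets differed, 496 higher and 196 lower at 24 h, with 2896 at an unadjusted p under 0.05. Vehicle cancels in this comparison, so effects of hour and hybridisation run remain in it; runs here are those inferred from the instrument records. Its spread came from the vehicle arrays and from the 2 drugs within an hour. In the next fit each vehicle array had its own term, so the spread came from the 2 drugs alone. Drugs at different doses thus stand in for replicates. That fit also takes in the single vehicle arrays of 4 and 24 h, so its count cannot be set directly against 692. With the difference between the vehicle arrays of these hours subtracted, 0 probe sets passed (limma, 3 residual degrees of freedom; 1226 at an unadjusted p under 0.05; smallest adjusted p 0.115). Among 23 lists, 7 were called with the preset correlation and 0 with an estimated one; with vehicle subtracted 6 and 0 were. Acute phase and interferon genes were higher at 24 h by a median of 1.16 (camera adjusted p = 3.21e-14), macrophage and leukocyte genes by 0.90 (adjusted p = 2.81e-10) and the IL-1 and NF-kB list by 0.48 (adjusted p = 0.000492). Of the IL-1 and NF-kB list 8 genes were called higher at 24 h and 2 lower. The 2 were Il1a itself (-1.24 ± 0.31, limma adjusted p = 0.041) and Cxcl1 (-1.78 ± 0.41, adjusted p = 0.0267). Leydig cell genes were lower, with a median of -0.43 (adjusted p = 0.0106), as were elongating spermatid genes at -0.14 (adjusted p = 6.44e-08), round spermatid genes at -0.11 (adjusted p = 0.0229) and glycolysis genes at -0.09 (adjusted p = 0.0491). Random lists of equal size and brightness had medians of -0.10, -0.09 and -0.07 beside the elongating spermatid, round spermatid and glycolysis lists, and 76, 1672 and 2933 of 10000 lay as low. With vehicle subtracted the round spermatid list was not called (adjusted p = 0.762), and the medians of the others were 1.18, 0.92, 0.83, -0.59, -0.11 and -0.11 for acute phase, leukocyte, IL-1, Leydig, elongating spermatid and glycolysis genes; 1803 and 1088 of 10000 random lists lay as low as the last 2. With an estimated correlation the smallest adjusted p was 0.112, and 0.592 with vehicle subtracted.

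At 24 h, 4 of 16 Leydig list members, Cyp17a1, Cyp11a1, Lhcgr and Hsd3b1, were called lower with both drugs; Hsd3b1 was named after its values were seen. Star and Akr1c14 were higher on both arrays, which a loss of Leydig cells alone would not give. A rise of these genes over a loss of cells would look the same, so they cannot decide this. Insl3 was lower by -0.99 with gamendazole and -0.79 with lonidamine. Of the 16 members, 12 were lower and 4 higher with gamendazole, and 9 lower and 7 higher with lonidamine. As the whole cause, a loss of cells would lower genes made only in them alike. The 4 called genes ranged from -5.10 or lower (Cyp17a1) to -1.20 (Hsd3b1) with gamendazole and from -4.19 to -1.20 with lonidamine. These values rest on 1 array of each drug, and whether other cells make these genes was not measured. The tables therefore leave fewer Leydig cells open as part of the cause. They argue against scaling between the arrays, since 4 stayed called under quantile normalization and under cyclic loess. They argue against a high 24 h vehicle array as the whole cause: 6 members at least 2-fold below that array on both had medians of -2.12 with gamendazole and -1.38 with lonidamine against the other 3 vehicle arrays (-2.41 and -1.60 against the 24 h array), each below 0 by more than its standard error, and the 4 called stayed called, while Hsd17b3 and Nr5a1 were called on both in neither fit. A lower transcription of the 4 genes may remain as an explanation and was not tested.

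At 24 h, 7 of 26 leukocyte genes were called higher with both drugs: Cd53, Lyz2, RT1-Da, Fcgr2b, C1qa, Lcp1 and Cd163, named after their values were seen. The tables argue against the hybridisation run of the 24 h arrays, since the list median over the vehicle array of the same run was 0.75 or more. More blood stays open: above Hbb, in ratios to the 24 h vehicle array, by more than the standard error from the fit against the 4 vehicle arrays lay 2 of the 7 on gamendazole 24 h and 6 on lonidamine 24 h, where all 7 lay above it (0.80 to 3.04, against 0.49), and the 4 erythrocyte genes had medians of -0.08 and 0.13. Entry of leukocytes may contribute and stays open as well, since of 6 genes expressed across leukocytes (Ptprc, Itgb2, Tyrobp, Laptm5, Cd53 and Coro1a) 1, Cd53, was called higher on both, while all 6 lay above the 24 h vehicle array on both (0.03 to 2.69 with gamendazole and 0.28 to 2.16 with lonidamine).

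The IL-1 and NF-kB list was higher with gamendazole than with lonidamine at 4 h and lower at 24 h, by medians of 0.66 and -0.54. A fixed lower exposure to lonidamine would keep the list higher with gamendazole, but -0.54 is itself part of the pattern and rests on 1 array of each drug, so this stays open. The hybridisation run of the gamendazole 4 h array is argued against by a median of 1.19 over the vehicle array of its own run. A slower response to lonidamine may be the source and stays open. Immediate early genes went from 0.47 at 4 h to -0.21 at 24 h, but on the same arrays, so they are no separate evidence. Leydig cell genes (0.757 and -0.455) and acute phase genes (0.292 and -0.595) turned as well, while leukocyte genes did not (0.369 and 0.024). The Leydig turn was of another kind. Over vehicle, that list went from 0.723 at 4 h to -0.845 at 24 h with gamendazole, and from -0.165 to -0.5 with lonidamine. Drug levels were not measured, and 1 array per hour cannot tell such a delay from differences between animals.

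Slc3a1 was lower than vehicle with gamendazole and higher with lonidamine at all 3 hours (averaged difference between the drugs -1.64); the opposite directions at single hours were not tested, 1 of 158 named genes showed them, and this gene had been named for its difference between the drugs. The rat GAPDH control probe sets, which no comparison used, had signals on gamendazole 24 h of 6410.4 (3' end), 7519.1 (5' end) and 6007.2 (middle), above all 4 vehicle arrays, as on lonidamine 24 h; they are 3 of 9 rat control probe sets looked at.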

How the results depend on the processing

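The alternatives with the hybridisation run as a factor, with gamendazole 4 h left out, with probe sets at the floor on all vehicle arrays left out and with each treated array alone against 3 vehicle arrays were chosen after seeing the data, as were the comparisons of the 24 h with the 4 h arrays; the other alternatives were planned. For single genes and lists called in the reported averaged comparisons and for genes lowest at 24 h, 655 values were taken, of which 444 kept direction and side of the threshold, 210 kept the direction but were no longer called, and 1 reversed: the round spermatid list with gamendazole under cyclic loess (camera adjusted p = 0.981). Averaged genes and lists under the alternatives chosen after seeing the data are not among these 655; of the lists, 1 lost its call there, macrophage and leukocyte genes in the direct comparison with the run in place of the hour on the same 9 arrays (0.0588). The 3 germ cell lists lost their calls with both drugs under quantile normalization and cyclic loess. Among named genes not called, 67 values with gamendazole and 50 with lonidamine gained a call and 64 and 67 changed sign; among lists not called, 22 and 23 gained a call and 17 and 9 changed direction. In the direct comparison 12 list values gained a call and 43 changed direction. Of 215 counts and correlations, 114 stayed within 1.5 times the reported count or 0.1 of the reported correlation and 101 moved. The 62 named genes called with gamendazole and 20 with lonidamine had the same sign in every alternative. None of them could be called in every alternative, since no probe set passed with no filter or without the 12 h arrays. For genes, these settings also add to the 210 values no longer called. The causes were not tested. Signal over background limits the genes at the floor, whose folds are lower bounds.

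In the averaged comparisons with vehicle, the counts for gamendazole and lonidamine were 247 and 1 with a floor at the 50th percentile, 0 and 0 with no filter (limma; 4099 and 2775 at an unadjusted p under 0.05), 28 and 2 without the variance trend, 372 and 50 with no hour factor, 242 and 4 with the actin ratio, and 1162 and 225 with gamendazole 4 h left out. The count for gamendazole was 205 with the run in place of the hour on the same 9 arrays and 272 with the 0 h vehicle array added as well, and that for lonidamine 55 with the 75th percentile filter. Leaving out an hour gave 0 to 1646 for gamendazole, 0 to 600 for lonidamine and 0 to 2 for the direct comparison, which had 8 with gamendazole 4 h left out.

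Against the 4 vehicle arrays, leaving out a vehicle array gave 33 to 132 with gamendazole and 1 to 11 with lonidamine at 4 h, 676 to 1021 and 72 to 178 at 12 h, and 818 to 1310 and 616 to 940 at 24 h. Without the trend the counts were 17 and 1, 789 and 96, and 753 and 696. At 4 h the counts with gamendazole and lonidamine were 351 and 21 under cyclic loess, 318 and 20 with the floor at the 10th percentile, 307 and 160 with that at the 50th, 569 and 509 with no filter, and 367 and 26 without probe sets at the floor; lonidamine had 8 under quantile normalization and 20 with the 75th percentile filter. At 12 h lonidamine had 379, 460, 587 and 425 with the low floor, the high floor, no filter and without probe sets at the floor.

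Counts of at least 2-fold, for gamendazole and lonidamine at 4, 12 and 24 h in turn, were 342, 151, 834, 385, 935 and 801 with the high floor, 1958, 1674, 2760, 2046, 2817 and 2271 with no filter, and 155, 50, 450, 186, 490 and 425 with the 75th percentile filter. Vehicle pairs gave 69 to 106, 1385 to 1782 and 9 to 28 in these settings. Over the mean of 4 vehicle arrays the counts were 548 and 326 at 4 h and 628 with lonidamine at 12 h, with a vehicle background of 238 to 320. Vehicle arrays over 0 h gave 106, 93 and 94 with the high floor.

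Lists called with an estimated correlation were 0 for each drug and for the direct comparison, and with fry 6 for gamendazole, 2 for lonidamine and 0 for the direct comparison. With gamendazole these were the immediate early (fry adjusted p = 0.0144), adhesion and barrier (0.038), IL-1 and NF-kB (0.0439), meiotic (0.0439), heat shock (0.0439) and p53 lists (0.0439). With lonidamine they were the immediate early and the adhesion and barrier lists (fry adjusted p = 0.0206 for each). The direct comparison had 1 with the high floor, 0 with no filter, 1 with the 75th percentile filter, 1 with the run in place of the hour on the same 9 arrays, 4 with gamendazole 4 h left out and 0 to 6 without an hour; leaving out an hour gave 8 to 11 for gamendazole and 9 to 10 for lonidamine. The correlation of the drugs' effects was 0.539 with the 0 h vehicle array as the reference of lonidamine.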

Other observations

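The tests on splits in this part were chosen after the result was seen; the lists were planned. Xbp1, Mcl1, Cdkn1a and Tpi1 were named after their values were seen. In the ER and integrated stress list, Ppp1r15a, which restores translation after stress, rose 4.62-fold with gamendazole and 4.01-fold with lonidamine (limma adjusted p = 0.00828 and 0.0318). Atf4, Vegfa and Xbp1 rose with gamendazole, while Phgdh, of serine synthesis, fell by 0.99; of 26 genes 4 rose and 1 fell with gamendazole (4 and 5 when adjusted over the list alone; camera adjusted p = 0.914) and 1 rose with lonidamine (3 rose and 1 fell when adjusted over the list alone; adjusted p = 0.616). Of 20 NRF2 genes, Srxn1, which repairs peroxiredoxins, rose 2.33-fold and 1.85-fold, and Hmox1, which breaks down haem, rose 2.35-fold with gamendazole and did not pass with lonidamine (0.84 ± 0.21, limma adjusted p = 0.117). With Gstp1, that list had 3 and 1 risen (5 and 3 when adjusted over the list alone; camera adjusted p = 0.0606 and 0.133; with gamendazole 0.0336 and 0.0498 and called higher under quantile normalization and cyclic loess). Of 19 p53 and apoptosis genes 4 and 1 rose, namely Ccng1, a cyclin induced by p53, by 1.23 ± 0.23, Bcl2l11, Mcl1 and Cdkn1a with gamendazole, and Mcl1 with lonidamine. Adjusted over the list alone, 4 rose and 1 fell with gamendazole and 3 rose with lonidamine. The list was not called (camera adjusted p = 0.0565 and 0.074). It was called higher with both drugs under quantile normalization (camera adjusted p = 0.0276 and 0.0367), cyclic loess (0.0412 and 0.0449) and the floor at the 50th percentile (0.0231 and 0.0196). With gamendazole it was also called higher with the 75th percentile filter (camera adjusted p = 0.0278), without the 4 h arrays (0.0391) and with gamendazole 4 h left out (0.0419).

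Of 14 growth factor genes of the tubule, Fst, which binds activin, rose 2.82-fold and 2.74-fold with gamendazole and lonidamine (limma adjusted p = 0.00794 and 0.0254); Tgfb3 also rose and Inhbb fell with gamendazole, so that 2 rose and 1 fell, and 1 rose with lonidamine (4 rose and 1 fell, and 3 rose, when adjusted over the list alone; camera adjusted p = 0.287 and 0.0678). Of 15 glucocorticoid response genes Dusp1, Angptl4 and Cdkn1a rose with gamendazole (4 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.122). Of 19 clock genes 2 rose with each drug, also when adjusted over the list alone (camera adjusted p = 0.639 and 0.641): Nfil3 by at least 2.60 and 2.33 and Bhlhe40 by 2.34 and 2.07 on the log2 scale, both of them repressors of transcription. Of 20 cholesterol synthesis genes 0 passed with either drug, also when adjusted over the list alone (camera adjusted p = 0.0582 and 0.0515; with lonidamine 0.0485 and 0.0449 and called higher under quantile normalization and cyclic loess, with gamendazole 0.0313 without the 24 h arrays, and 0.0378 and 0.0365 with the run in place of the hour on the same 9 arrays). Of 27 glycolysis and lactate transport genes, Pgk1 rose by 0.82 and Tpi1 fell by 0.31 with gamendazole (1 rose and 5 fell when adjusted over the list alone; camera adjusted p = 0.177, but 0.0139 and called lower without the 4 h arrays), and 0 passed with lonidamine, also over the list alone (adjusted p = 0.142).

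Other ways of dividing the 6 arrays of a comparison into 3 and 3 make 10 splits with the real one, too few for a share under 0.05. For gamendazole against vehicle 1 of 10 splits gave as many calls, with 693 in the real split and 0 as the highest other. For lonidamine it was 1 of 10, with 137 and 35. For gamendazole against lonidamine the real split gave 0, so that 10 of 10 splits give as many whatever the data and the count says nothing. The highest other gave 100 and set lonidamine 4 h, gamendazole 4 h and lonidamine 12 h against the rest. With the hour kept as a factor, that split compares lonidamine 12 h with gamendazole 12 h directly within their hour. It also sets the response over vehicle at 4 h against that at 24 h. Its count of 100 therefore cannot be put down to either comparison alone.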
